A study of Arabidopsis thaliana with 10 samples.

How the data were processed

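Total RNA of Arabidopsis thaliana seedlings was hybridised by the submitters to Affymetrix ATH1 arrays, 10 arrays in 5 groups of 2. Per the labels, RNA was purified with a column kit and labelled with biotin, and plants grew on plates at 23 and 18 °C. The labels give leaf tissue and 20 days of age, and the series text gives seedlings of 14 days. The text calls the 2 arrays of a group biological replicates. The time of day of harvest is not given in the sources used here.

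The deposited values are log2 signals that the authors made with GCOS and RMA, without stated versions, per the labels. RMA corrects background, normalises quantiles and summarises the probes of a probe set. Whether all 10 arrays went through RMA together is not stated. All columns of the value table were mapped to a sample. No pseudocount was used because the values were already logarithms.

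Of 22810 probe sets, 64 controls were set aside and 22746 were tested without a filter. No detection call was used, so a signal under the lower quartile of its array is not shown to be above background and is called the background range. A gene was named where the probe annotation gives exactly 1 gene (13513 probe sets, 13350 genes), with locus codes from RefSeq for TAIR10.1 (13436 probe sets matched, 77 not). A further 503 probe sets carry several genes and 8730 none, so named genes are a part of those measured. CBF1, CBF2 and CBF3, which the naming rule asked for, have no named probe set of their own, and their results are not reported here.

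One linear model with 5 group means was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), since groups of 2 need a pooled estimate of spread. The 7 comparisons were 24 h of cold in Col, 3 h and 24 h of cold in C24, 24 h against 3 h in C24, C24 against Col at room temperature and after 24 h of cold, and the difference of the 24 h responses. P-values were adjusted by Benjamini-Hochberg within each comparison, with an adjusted p below 0.05 as the threshold and the subset changed at least 2-fold given beside it.

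Genes named were, among called probe sets with 1 gene and non-overlapping arrays, the 8 largest changes each way in each comparison of cold with room temperature, the 6 largest each way between ecotypes and for the difference of responses (without the array condition there), and the 5 largest each way between 24 h and 3 h. Of a gene list, the 2 largest rises and 2 largest falls could be named, or all members of a list of at most 5.

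Gene lists were tested with camera (limma) at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Of 18 lists fixed before the data were examined, 6 had at least 3 measured members. Another 24 lists were drawn afterwards from the annotation's gene symbols, the last 2 (a wider root list and branched-chain amino acid breakdown) after the leading genes were seen. Adjustment ran over the 42 tests of the first kind and, separately, over the 168 of the second. A gene with several probe sets was represented by the one with the highest mean.

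Overlaps of calls were set against independent lists and against 20 simulations of unchanged groups. Control probe sets were averaged per array and compared between ecotypes by an exact permutation test over all 210 splits.

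Tested on simulated data with 200 changed probe sets per comparison, the fit recovered 82.1 to 94% of log2 changes of 0.5 between groups and 29.9% for the difference of responses. Of log2 changes of 1 it recovered 98.5 to 100%, with 7 to 14 false calls per comparison. Camera called 10 of 10 shifted lists and 0 of 40 unshifted lists. The simulated probe sets varied independently of each other, so these runs do not show how camera at the preset correlation behaves with correlated genes.

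Alternatives were another quantile normalisation, median centring, the replicate number as a block, an intensity trend with a robust prior, dim probe sets left out, 1 probe set per gene, only the arrays of the groups compared, a 2-fold threshold and each array left out in turn. Alternatives chosen after the data were seen left out the C24 room temperature arrays, exchanged replicate numbers of 1 group, or counted calls that did not rest on those arrays.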

Results

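Transcript levels were measured on 10 arrays of 1 colour carrying 22746 non-control probe sets of Arabidopsis thaliana. They came from plate-grown seedlings of the ecotypes Col, from which the reference genome was made, and C24, another natural accession. The series is titled as a comparison of ecotypes in their response to cold, and cold means 4 °C here. The 5 groups were Col at room temperature, Col after 24 h of cold, C24 at room temperature, C24 after 3 h of cold and C24 after 24 h of cold, with 2 arrays each and no Col arrays at 3 h. The sample labels give leaf tissue and an age of 20 days, whereas the series text speaks of seedlings aged 14 days. The values are deposited RMA signals on the log2 scale, and every change below is a difference of log2 signals. Genes called largest or leading in a comparison are ranked only among called probe sets with exactly 1 named gene. Depending on comparison and direction, 18 to 38 of the 50 largest called changes had no single gene and are not named. With 2 arrays per group, the number of arrays limits the precision: the median SE of a difference between groups was 0.0878, and that of the difference of responses was 0.124.

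Replicate arrays lay close together, with a median SD per probe set from 0.0534 in C24 after 24 h to 0.0695 in Col after 24 h. Across probe sets, which are not independent replicates, their Pearson correlation lay between 0.99725 and 0.99829. The C24 arrays at room temperature lay farther from the Col arrays at room temperature (root mean square difference of group means 0.761) than C24 lay from Col after 24 h of cold (0.604). The C24 arrays after 3 h of cold lay nearer to Col at room temperature (0.629) than the C24 room temperature arrays did. Poly-A spike-in controls, bacterial transcripts added to each RNA sample, were higher on the C24 arrays (7.09 ± 0.11, SD, n = 6) than on the Col arrays (5.76 ± 0.02, SD, n = 4), with an exact two-sided permutation p of 0.00476. Controls added at hybridisation did not separate them at the threshold (9.94 ± 0.12 against 10.11 ± 0.11, exact two-sided permutation p = 0.0571). The difference between the 3' and 5' GAPDH control probe sets, which grows with RNA degradation, was 0.68 ± 0.26 (SD, n = 2) in C24 at room temperature and 0.20 ± 0.15 in Col at room temperature. It was 0.49 ± 0.11 and 0.38 ± 0.01 in C24 after 3 h and 24 h, and 0.14 ± 0.05 in Col after 24 h. Every C24 array lay above every Col array, with the lowest C24 array at 0.374 (24 h) and the highest Col array at 0.314 (room temperature).

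**Figure D1:**
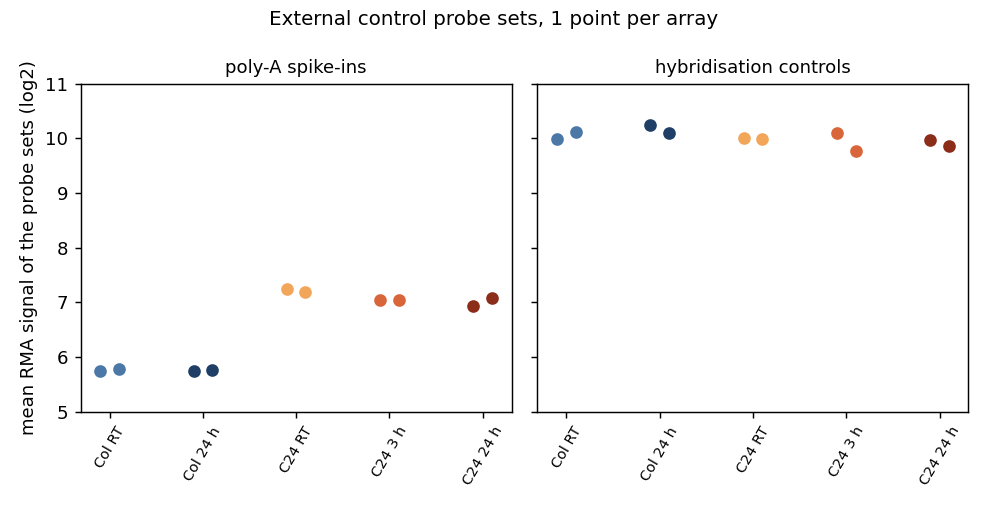
Mean log2 RMA signal of 12 poly-A spike-in probe sets (left) and 9 hybridisation control probe sets (right) on each of the 10 arrays, 1 point per array, RT for room temperature. The spike-in means of the C24 arrays lie between 6.94 and 7.24 and those of the Col arrays between 5.74 and 5.78.

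In Col, 24 h of cold was compared with room temperature. The largest rise among named genes was that of COR27 (AT5G42900), a cold-induced gene with evening expression, from 3.83 ± 0.18 to 10.97 ± 0.06 (SD, n = 2). Its room temperature level lay under the lower quartile of all probe sets on those arrays (4.5 and 4.51), as did that of AT2G38465, so neither is shown to be above background. AT5G62360 rose by 5.89, AT4G33980 by 5.43, AT1G16850 by 5.34, AT3G55580 by 5.10, AT1G51090 by 4.65, the defensin-like gene PDF2.1 (AT2G02120) by 4.25 and AT2G38465 by 4.21. The largest fall was that of AT1G13650, from 9.48 ± 0.07 to 4.42 ± 0.04, and the cold levels of this gene and AT1G52000 lay in the same background range. The other leading falls included those of the expansins EXPA8 (AT2G40610, -4.26) and EXPB1 (AT2G20750, -3.82) and the endoglucanase GH9B13 (AT4G02290, -3.26). As a list, 25 expansins and xyloglucan transferases were not called in Col, with 8 higher and 11 lower (camera adjusted p = 0.672). DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, fell by 4.17, and AT1G52000 (-3.68), AT1G67750 (-3.30) and AT4G15390 (-3.22) fell too. The SEs of these 16 changes ran from 0.07 to 0.20, and their adjusted p-values from limma from 3.66e-12 to 2.77e-08.

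Among the lists fixed before the data were examined, all 4 measured COR and LEA genes of freezing tolerance rose in Col, also when adjusted over the list alone. These are the chloroplast proteins COR15A (AT2G42540, 2.59 ± 0.08, SE) and COR15B (AT2G42530, 3.54 ± 0.07) and the dehydrins COR47 (AT1G20440, 2.84 ± 0.07) and LTI30 (AT3G50970, 2.90 ± 0.09). The set test camera gave the list an adjusted p of 5.28e-05 (adjusted p = 0.135 with an estimated correlation). A probe set shared by the cold-induced genes KIN1 and KIN2 rose by 1.97 ± 0.07 and cannot be assigned to either. All 4 measured genes of anthocyanin synthesis fell, also when adjusted over the list alone: DFR, the glycosyltransferases UF3GT (AT5G54060, -2.45) and AT4G14090 (-1.99), and the malonyltransferase AT5MAT (AT3G29590, -1.45). The camera adjusted p was 0.000241 (adjusted p = 0.123 with an estimated correlation). A wider flavonoid list of 10 genes, drawn later, was not called in Col (median -0.06). The fall is thus shown for the 4 anthocyanin genes only. Of the 4 measured photosynthesis antenna and photosystem genes, 3 fell (camera adjusted p = 0.0834), and 3 of 3 root-enriched genes fell (camera adjusted p = 0.0541), with the same counts adjusted over the list alone. Without Col room temperature replicate 2 the falls of the antenna gene LHCB4.1 (AT5G01530, limma adjusted p = 0.0708) and the root hair expansin EXPA7 (AT1G12560, 0.13) missed the threshold, and so did that of EXPA7 without Col 24 h replicate 2 (0.0551). The zinc finger factor STZ (AT1G27730) was the 1 measured member of the list of early cold transcription factors and rose by 2.34, and the clock gene GI (AT1G22770), the 1 measured member of the clock list, rose by 2.26.

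Lists drawn later from the annotation gave further groups in Col. Of 14 genes of ribosome biogenesis and RNA polymerases I and III, 12 rose and none fell (median 0.75, camera adjusted p = 5.75e-05, adjusted p = 0.131 with an estimated correlation), led by the polymerase I subunit NRPA1 (AT3G57660, 1.37) and the rRNA processing factor YAO (AT4G05410, 1.22). Of 15 glucosinolate and ER-body genes, 13 fell and 1 rose (median -1.02, camera adjusted p = 3.55e-06, adjusted p = 0.0914 with an estimated correlation). The largest falls there were those of the jacalin-related lectins JAL23 (AT2G39330, -3.17, to the background range) and JAL22 (AT2G39310, -2.14). By contrast, the 3 measured glucosinolate genes fixed beforehand had a median of 0.19 and were not called as a list. A fall of glucosinolate synthesis as such is thus not shown. Nuclear photosynthesis genes fell in 20 of 32 cases and rose in 2 (camera adjusted p = 0.000206, adjusted p = 0.0914 with an estimated correlation), with the porphyrin enzyme HEME1 (AT3G14930) at -1.21 and the chlorophyll enzyme CHLM (AT4G25080) at -0.96. Of 32 plastid-encoded genes of expression and the NDH complex, 19 fell and none rose (camera adjusted p = 0.000751, adjusted p = 0.637 with an estimated correlation), led by rps18 at -1.57. Of 33 plastid-encoded photosynthesis genes, 11 fell and 1 rose (camera adjusted p = 0.004, adjusted p = 0.648 with an estimated correlation, fry adjusted p = 0.0697). Dehydrin, LEA and desiccation genes rose in 9 of 17 cases and fell in 4 (camera adjusted p = 0.00202, adjusted p = 0.141 with an estimated correlation). The falls included HIS1-3 (AT2G18050), a drought-inducible linker histone, at -1.92. Of 13 heat shock and chaperone genes, 8 rose and 2 fell (camera adjusted p = 0.0216, adjusted p = 0.202 with an estimated correlation). Of 22 genes of cell division and DNA replication, 13 fell and 3 rose (camera adjusted p = 0.0332, adjusted p = 0.176 with an estimated correlation). Of the lists chosen after the leading genes were seen, the wider root list fell in 9 of 14 cases and rose in 2 (camera adjusted p = 0.0455, adjusted p = 0.417 with an estimated correlation), and branched-chain amino acid breakdown fell in 5 of 10 cases and rose in none (camera adjusted p = 0.0336, adjusted p = 0.223 with an estimated correlation). With dim members left out, the calls of cell division (adjusted p = 0.133), wider root (0.406) and branched-chain breakdown (0.08) were lost.

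By limma with Benjamini-Hochberg adjustment over 22746 probe sets, 11174 were called at an adjusted p below 0.05 in Col after 24 h, 5282 higher and 5892 lower. Of these, 1906 changed at least 2-fold, 965 higher and 941 lower. The balance of calls turned with arrays centred on their medians, to 5952 higher and 5415 lower.

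In C24, 24 h of cold was compared with room temperature. SWEET13 (AT5G50800), a sucrose transporter, rose from 6.13 to 10.40 (SDs 0.185 and 0.124, n = 2), a 19.2-fold change, and HYH (AT3G17609), a bZIP factor of light signalling, rose from 5.34 ± 0.34 to 9.61 ± 0.01. AT1G80130 rose by 3.60, CHIL (AT5G05270), a chalcone isomerase-like protein of flavonoid synthesis, by 3.60, AT3G55580 by 3.59, AT5G62210 by 3.59, the dehydrin LTI30 by 3.59 and the predicted glycosyltransferase gene AT2G16890 by 3.34. The largest fall was that of AT5G19120, from 11.01 ± 0.08 to 5.94 ± 0.14. The other leading falls were those of AT1G23390 (-4.63), EXPA8 (-4.45), AT3G28270 (-4.11), AT1G51400 (-3.97), AT3G26510 (-3.87), AT3G15630 (-3.87) and AT3G47560 (-3.80). The SEs of these 16 changes ran from 0.07 to 0.20, and their limma adjusted p-values from 2.23e-11 to 8.02e-09.

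The 4 measured COR and LEA genes rose in C24 too, also when adjusted over the list alone: COR15A by 1.67 ± 0.08 (SE), COR15B by 1.41 ± 0.07, COR47 by 1.49 ± 0.07 and LTI30 by 3.59 ± 0.09 (camera adjusted p = 0.00045, adjusted p = 0.155 with an estimated correlation). The probe set shared by KIN1 and KIN2 rose by 2.11 ± 0.07. The 4 anthocyanin genes rose, also when adjusted over the list alone: AT5MAT by 1.43, DFR by 1.16, UF3GT by 0.99 and AT4G14090 by 0.535 (camera adjusted p = 0.00567, adjusted p = 0.135 with an estimated correlation). On the wider flavonoid list drawn later, 9 of 10 genes rose and none fell (median 1.66, camera adjusted p = 2.66e-06, adjusted p = 0.0914 with an estimated correlation), with the flavonol glycosyltransferase UGT78D3 (AT5G17030) up by 2.84 from the background range. The 4 measured photosynthesis antenna and photosystem genes fell, also when adjusted over the list alone, with LHCB4.2 (AT3G08940) at -1.07 (camera adjusted p = 0.0408, adjusted p = 0.176 with an estimated correlation, 0.106 with dim members left out). The call of PSBY (AT1G67740) among them was lost after another quantile normalisation (limma adjusted p = 0.116). Of 3 root-enriched genes, 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.0933). STZ fell by 1.14 and GI rose by 1.01.

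Of 32 nuclear photosynthesis genes, 29 fell and none rose in C24 (median -0.53, camera adjusted p = 3.11e-09, adjusted p = 0.0914 with an estimated correlation). CHLM fell by 1.72 and PGRL1B (AT4G11960), a protein of cyclic electron flow, fell by 1.67. Plastid-encoded photosynthesis genes fell in 12 of 33 cases and rose in none (camera adjusted p = 0.00948, adjusted p = 0.69 with an estimated correlation). Of 14 ribosome biogenesis and polymerase genes, 11 rose and 1 fell (camera adjusted p = 3.71e-05, adjusted p = 0.129 with an estimated correlation), with YAO up by 1.97 and NRPA1 by 1.94. Of 10 autophagy genes, 8 fell and none rose (median -0.71, camera adjusted p = 0.00119, adjusted p = 0.246 with an estimated correlation), with ATG8E (AT2G45170) at -2.93 and ATG8F (AT4G16520) at -2.06. All 10 members of the list of branched-chain amino acid breakdown, chosen after the leading genes were seen, fell (camera adjusted p = 8.07e-05, adjusted p = 0.106 with an estimated correlation). They included MCCA (AT1G03090), a subunit of methylcrotonyl-CoA carboxylase, at -1.84, and AKINBETA1 (AT5G21170), a subunit of the SnRK1 kinase and not itself a breakdown enzyme, at -2.61. Dehydrin, LEA and desiccation genes rose in 12 of 17 cases and fell in 4 (camera adjusted p = 0.0158, adjusted p = 0.206 with an estimated correlation). Calmodulin-like and touch genes fell in 6 of 9 cases and rose in none (camera adjusted p = 0.0185, adjusted p = 0.164 with an estimated correlation). Glucosinolate and ER-body genes fell in 9 of 15 cases and rose in 2 (camera adjusted p = 0.0305, adjusted p = 0.206 with an estimated correlation). With dim members left out, the calls of the dehydrin list (adjusted p = 0.22) and of the glucosinolate and ER-body list (0.125) were lost.

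The limma fit called 11254 probe sets in C24 after 24 h, 5476 higher and 5778 lower, of which 1332 rose and 1164 fell at least 2-fold. With arrays centred on their medians, more were higher (5823) than lower (5448). Of the 11254, 6714 also lay beyond Col at room temperature in the same direction past the threshold, a count chosen after the data were seen because the ecotypes lay further apart at room temperature than after 24 h of cold.

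In C24, 3 h of cold was compared with room temperature. The leading rises included genes of cell wall remodelling: the xyloglucan transferase XTH19 (AT4G30290) rose from 4.55 ± 0.27 to 9.68 ± 0.10 (SD, n = 2), and the expansin-like gene EXLA1 (AT3G45970) rose by 3.58. AT1G52070 rose by 3.79 from the background range, AT4G30170 by 3.73, AT5G65300 by 3.70, AT1G49220 by 3.51, AT4G11190 by 3.50 and AT4G36010 by 3.42. The largest fall was that of AT3G23880, from 9.72 ± 0.12 to 5.19 ± 0.10. The other leading falls were those of AT1G23390 (-4.21), AT3G26510 (-4.15), AT5G19120 (-3.60), AT1G78450 (-3.28), AT1G31690 (-3.15), AT2G05160 (-2.88) and ORA47 (AT1G74930, -2.86), an AP2/ERF factor of jasmonate signalling. A second probe set of AT1G31690 gave -2.40. The SEs of these 16 changes ran from 0.07 to 0.20, and their limma adjusted p-values from 1.04e-10 to 4.51e-07.

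In Col at room temperature, XTH19 stood at 8.69 and AT1G52070 at 8.72, against 9.68 and 7.91 in C24 after 3 h of cold. AT3G23880 stood at 6.49 and AT5G19120 at 8.03 in Col at room temperature, below the C24 room temperature level of either gene.

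On the lists fixed beforehand, 3 of 3 root-enriched genes rose in C24 at 3 h, also when adjusted over the list alone: the root ER-body glucosidase PYK10 (AT3G09260) by 1.92 and the root hair expansins EXPA18 (AT1G62980) by 0.66 and EXPA7 by 0.61 (camera adjusted p = 0.0173, adjusted p = 0.16 with an estimated correlation, 0.106 with dim members left out). For all 3 genes the C24 room temperature arrays also lay below those of Col, by more than these rises. The call of EXPA7 was lost without C24 room temperature replicate 1 (limma adjusted p = 0.0653) and without C24 3 h replicate 2 (0.0595). Of the 4 COR and LEA genes, COR47 rose by 1.34 and LTI30 by 2.23, COR15A fell by 0.27, and COR15B stood at 0.13 ± 0.07 (SE), short of the threshold (camera adjusted p = 0.0871). The call of COR15A was lost without C24 room temperature replicate 1 (limma adjusted p = 0.1) and without C24 3 h replicate 1 (0.0662). The probe set shared by KIN1 and KIN2 fell by 0.19 ± 0.07. Of the 4 anthocyanin genes, 2 rose, AT5MAT by 0.83 and DFR by 0.36 (camera adjusted p = 0.215), and of the 4 photosynthesis genes LHCB4.1 and PSAN (AT5G64040) passed as lower (camera adjusted p = 0.585), with the same counts adjusted over the list alone. LHCB4.1 was lost without C24 room temperature replicate 1 (limma adjusted p = 0.0766) or C24 3 h replicate 2 (0.0676). PSAN was lost after another quantile normalisation (0.612), with only the arrays of the compared groups (0.0619), without C24 room temperature replicate 1 (0.137) or 2 (0.0836), without C24 3 h replicate 1 (0.119) or 2 (0.105), and without either C24 24 h array (0.0551). STZ rose by 0.75 and GI by 0.35.

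Of the lists drawn later, glucosinolate and ER-body genes rose in 12 of 15 cases and fell in none (median 0.85, camera adjusted p = 3.55e-06, adjusted p = 0.0914 with an estimated correlation), with NAI2 (AT3G15950), a protein of ER-body formation, up by 2.44. The 3 measured glucosinolate genes fixed beforehand had a median of 0.05 and were not called as a list. Of 25 expansins and xyloglucan transferases, 13 rose and 2 fell (camera adjusted p = 0.00821, adjusted p = 0.129 with an estimated correlation), and the falls were those of EXPA8 (adjusted p = 9.07e-06) and EXLB1 (AT4G17030, -1.09). Tau-class glutathione transferases rose in 9 of 11 cases and fell in 1 (camera adjusted p = 0.00421, adjusted p = 0.129 with an estimated correlation), led by GSTU22 (AT1G78340) with 1.83. Nuclear photosynthesis genes fell in 18 of 32 cases and rose in 1 (camera adjusted p = 0.00103, adjusted p = 0.106 with an estimated correlation). Ribosome biogenesis and polymerase genes rose in 8 of 14 cases and fell in 1 (camera adjusted p = 0.011, adjusted p = 0.231 with an estimated correlation). The wider flavonoid list had 5 of 10 genes higher and none lower (camera adjusted p = 0.0272, adjusted p = 0.215 with an estimated correlation). Family 1 glycosyltransferases rose in 19 of 46 cases and fell in 7 (camera adjusted p = 0.0203, adjusted p = 0.163 with an estimated correlation). Of the lists chosen after the leading genes were seen, the wider root list had 8 of 14 genes higher and 1 lower (camera adjusted p = 0.0111, adjusted p = 0.321 with an estimated correlation), and branched-chain amino acid breakdown had 6 of 10 lower and none higher (camera adjusted p = 0.0129, adjusted p = 0.2 with an estimated correlation). With dim members left out, the calls of the tau class (adjusted p = 0.0536), ribosome biogenesis (0.0651) and the wider flavonoid list (0.187) were lost.

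The limma fit called 10390 probe sets in C24 after 3 h, 5120 higher and 5270 lower, and at least 2-fold 1034 rose and 583 fell. The near-even split depended on the scaling: 4751 were higher and 6034 lower with arrays centred on their medians, and 4912 and 5624 after another quantile normalisation. Of the 10390, 4142 also lay beyond Col at room temperature in the same direction past the threshold, again a count chosen after the data were seen.

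**Figure D2:**
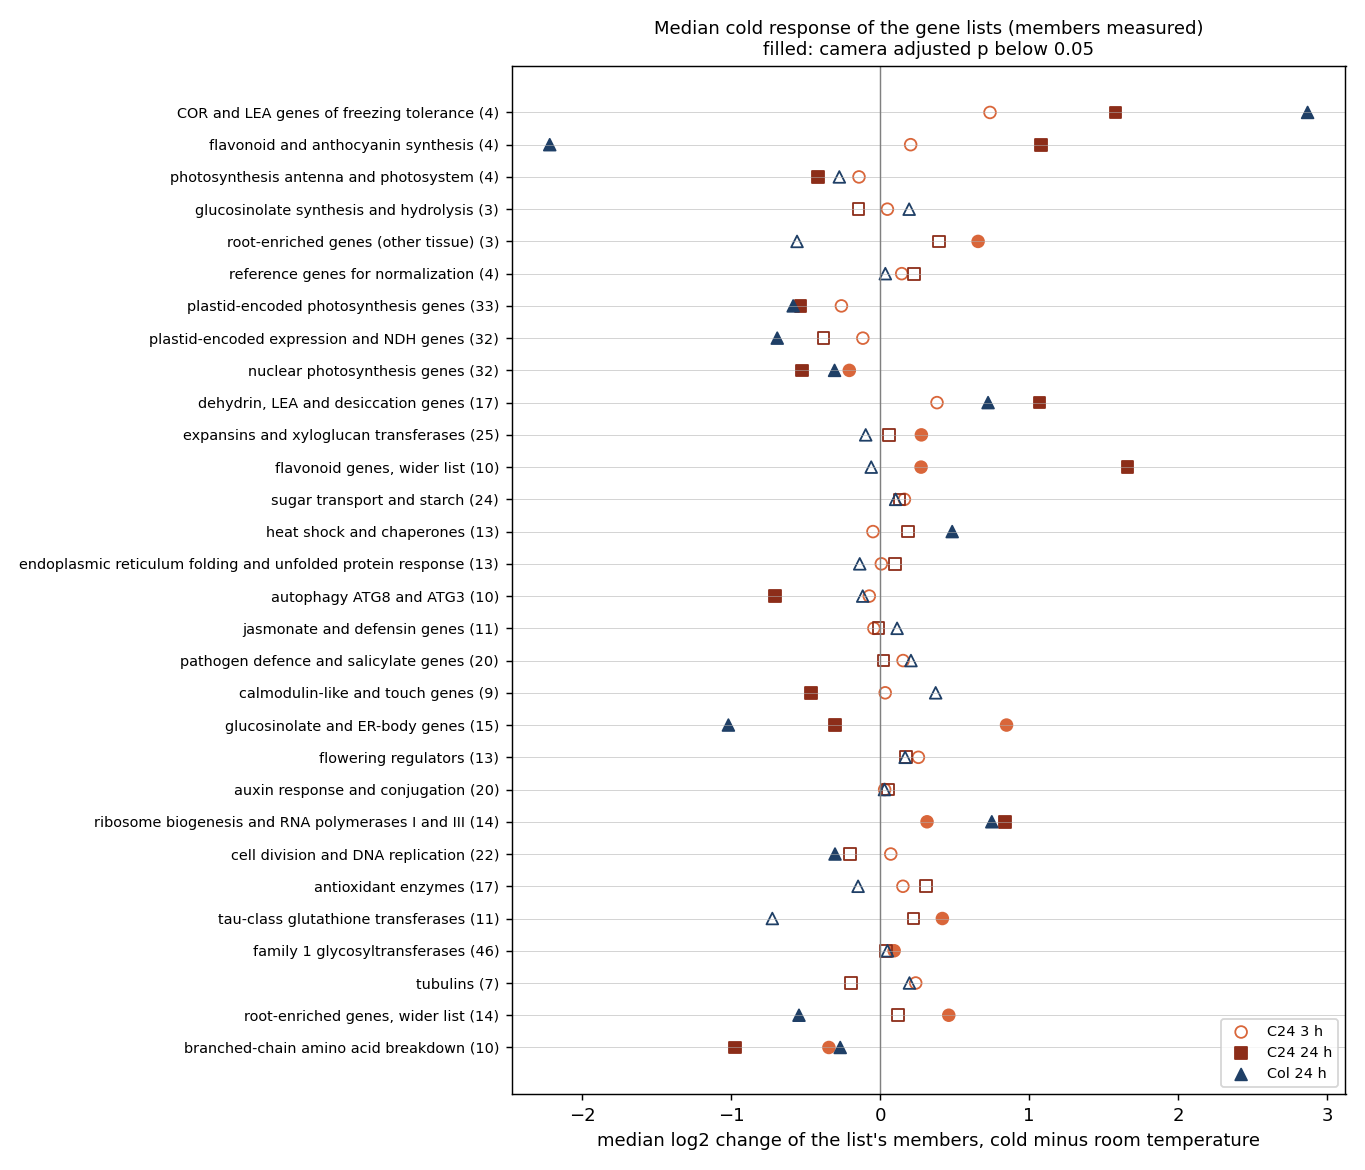
Median log2 change of each gene list (horizontal axis, cold minus room temperature) for C24 at 3 h (circles), C24 at 24 h (squares) and Col at 24 h (triangles), with the number of measured members in brackets and filled symbols where the camera adjusted p lay below 0.05 with the preset correlation. The anthocyanin list lies at 1.08 in C24 and -2.22 in Col after 24 h, and the COR and LEA list at 1.58 and 2.87.

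Between 3 h and 24 h of cold in C24, the defensin PDF1.2b (AT2G26020) rose from 6.22 ± 0.10 to 9.44 ± 0.15 (SD, n = 2). AT5G62210 rose by 3.15, AT1G80130 by 3.09, UGT78D3 by 2.78 and SWEET13 by 2.76. The leading falls were those of AT1G61500 (-3.69), AT1G62510 (-3.66), EXLA1 (-3.52), AT3G50270 (-3.43) and AT1G17960 (-3.37, to the background range), with SEs of the 10 changes from 0.07 to 0.17. The probe set of PDF1.2b carries the suffix that marks probes shared with other sequences. Glucosinolate and ER-body genes fell in 14 of 15 cases and rose in none (median -1.22, camera adjusted p = 3.11e-09, adjusted p = 0.0914 with an estimated correlation), and all 10 autophagy genes fell (median -0.68, camera adjusted p = 0.00011, adjusted p = 0.215 with an estimated correlation). Of the 4 COR and LEA genes 3 rose (camera adjusted p = 0.00301, adjusted p = 0.189 with an estimated correlation), and all 4 anthocyanin genes rose (camera adjusted p = 0.00829, adjusted p = 0.135 with an estimated correlation), with the same counts adjusted over the list alone. Of the wider flavonoid list, 9 of 10 genes rose and none fell (camera adjusted p = 3.55e-06, adjusted p = 0.0914 with an estimated correlation), and of 14 ribosome biogenesis and polymerase genes 11 rose and 2 fell (camera adjusted p = 0.000558, adjusted p = 0.163 with an estimated correlation). Nuclear photosynthesis genes fell in 22 of 32 cases and rose in 2 (camera adjusted p = 4.45e-06, adjusted p = 0.0914 with an estimated correlation). Calmodulin-like and touch genes fell in 6 of 9 cases and rose in none (camera adjusted p = 0.00382, adjusted p = 0.129 with an estimated correlation), with CML38 (AT1G76650) at -1.98, down to the background range, and STZ at -1.88. Branched-chain amino acid breakdown fell in 7 of 10 cases and rose in none (camera adjusted p = 0.00139, adjusted p = 0.131 with an estimated correlation). That list was chosen after the leading genes were seen. The limma fit called 10073 probe sets, 4946 higher and 5127 lower, of which 679 rose and 962 fell at least 2-fold. The balance of calls turned with arrays centred on their medians (6052 higher, 4494 lower) and after another quantile normalisation (5286 higher, 4899 lower).

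The responses were then set against each other. In C24, 854 probe sets changed at least 2-fold the same way at 3 h and at 24 h, 472 higher and 382 lower, where independent lists of these sizes would share 60.55 and 29.83. A further 9 were higher at 3 h and lower at 24 h, and 5 the opposite. At the adjusted p alone, 3157 were higher and 3401 lower at both times, against 1233 and 1339 for independent lists. Both comparisons use the same room temperature arrays: over 20 simulations of unchanged groups the mean correlation of fold changes was 0.501 and no probe set was called in both. Unchanged groups give hardly any calls, so the lack of shared calls there is no baseline for the overlap. The observed correlation across probe sets was 0.638, and the covariance was 0.246 against 0.00467 simulated. The control arrays could not be split with 2 in each part, so some of the excess may come from sharing them.

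The 24 h responses of C24 and Col, which share no array, had 616 probe sets changed at least 2-fold the same way, 361 higher and 255 lower, against 56.51 and 48.15 for independent lists. The same 2-fold threshold was passed in opposite directions by 66 probe sets that rose in C24 and fell in Col and by 84 that fell in C24 and rose in Col. At the adjusted p alone, 2781 were higher and 3081 lower in both, against 1272 and 1497. The correlation of the 24 h fold changes across probe sets was 0.369, and the covariance was 0.152 against 7.41e-06 in 20 simulations of unchanged groups. EXPA8 and AT3G55580 were among the leading genes of both ecotypes.

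C24 was compared with Col at room temperature. COR27 was higher in C24, at 10.93 ± 0.00 against a Col level of 3.83 ± 0.18 (SD, n = 2) in the background range, and its C24 level stayed between 10.73 and 10.93 in the 3 C24 groups. AT4G29200 was higher by 6.70, AT1G07050 by 6.11, AT4G33980 by 5.13, AT5G62360 by 4.65 and AT3G48640 by 4.46. The Col levels of AT4G29200, AT1G07050 and AT3G48640 and the C24 level of AT5G26260 lay in the background range too, so these differences and their ranks rest on levels not shown to be above background. ECS1 (AT1G31580) was lower in C24, at 4.67 ± 0.03 against 11.64 ± 0.01. The other leading genes lower in C24 were AT4G15390 (-5.65), AT5G26260 (-5.27), AT1G18980 (-5.19), AT4G30170 (-5.16) and AT5G38910 (-5.13). The SEs of these 12 differences ran from 0.07 to 0.16, with limma adjusted p-values from 1.79e-12 to 1.57e-10.

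All 3 root-enriched genes fixed beforehand were lower in C24 at room temperature, also when adjusted over the list alone: PYK10 (-2.20), EXPA18 (-2.04) and EXPA7 (-1.75) (camera adjusted p = 0.00301, adjusted p = 0.135 with an estimated correlation). Their rises at 3 h of cold used the same C24 room temperature arrays, so those rises are not independent of these differences. On the wider root list, 12 of 14 genes were lower and none higher (median -0.95, camera adjusted p = 6.12e-06, adjusted p = 0.163 with an estimated correlation). That list was chosen after the leading genes were seen, so its p-value is no independent support. All 4 anthocyanin genes were lower, also when adjusted over the list alone, with DFR at -2.97 and UF3GT at -1.93 (camera adjusted p = 0.00045, adjusted p = 0.123 with an estimated correlation). On the wider flavonoid list 8 of 10 were lower and 1 higher (camera adjusted p = 3.71e-05, adjusted p = 0.106 with an estimated correlation). Of the COR and LEA genes, COR15B (2.12) and COR15A (0.95) were higher and LTI30 (-1.86) and COR47 (-0.20) lower (camera adjusted p = 0.831). The call of COR47 was lost without Col room temperature replicate 1 (limma adjusted p = 0.147) and without C24 room temperature replicate 1 (0.0627) or 2 (0.102). It was also lost with arrays centred on their medians (0.0504) and with only the arrays of the compared groups (0.0598). GI was higher in C24 by 1.38 ± 0.08 (SE).

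Expansins and xyloglucan transferases were lower in 15 of 25 cases and higher in 4 (camera adjusted p = 0.000558, adjusted p = 0.106 with an estimated correlation), with XTH19 at -4.14 and XTH18 (AT4G30280) at -2.64. Glucosinolate and ER-body genes were lower in 10 of 15 cases and higher in 4 (camera adjusted p = 0.00147, adjusted p = 0.129 with an estimated correlation), with NAI2 at -3.57. The 3 measured glucosinolate genes fixed beforehand had a median of 0.26 and were not called as a list. The rises of the expansin list and the glucosinolate and ER-body list at 3 h used the same C24 room temperature arrays. Those rises are therefore not independent of the differences given here. Nuclear photosynthesis genes were higher in 20 of 32 cases and lower in 2 (median 0.29, camera adjusted p = 0.00473, adjusted p = 0.129 with an estimated correlation). Family 1 glycosyltransferases were lower in 22 of 46 cases and higher in 13 (camera adjusted p = 0.0204, adjusted p = 0.163 with an estimated correlation), and genes of cell division and DNA replication were lower in 10 of 22 cases and higher in 2 (camera adjusted p = 0.0336, adjusted p = 0.176 with an estimated correlation). With dim members left out, both of these calls were lost (adjusted p = 0.0913 and 0.14). The limma fit called 12749 probe sets, 7433 higher and 5316 lower in C24, and 1067 were at least 2-fold higher and 1476 at least 2-fold lower. The spike-in level differed between the ecotypes' arrays throughout (7.09 against 5.76), so a labelling batch and the ecotype cannot be told apart in this comparison or in the next. The GAPDH 3' minus 5' difference also separated the arrays by ecotype. RNA quality therefore cannot be told apart from the ecotype in these comparisons either, and the cause of that separation was not tested.

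After 24 h of cold, AT4G29200 was again far higher in C24 than in Col, at 11.52 ± 0.03 against 3.89 ± 0.16 (SD, n = 2). AT2G27420 was higher by 5.43, AT2G29170 by 4.78, AT5G15360 by 4.60, AT2G29370 by 4.58 and AT4G19430 by 4.22. ECS1 was again lower in C24 (-6.79), and so were the tau-class glutathione transferase GSTU25 (AT1G17180, -5.62), AT4G20480 (-4.74), AT1G19530 (-4.24), AT5G23830 (-3.89) and AT2G14460 (-3.82), with SEs of the 12 differences from 0.08 to 0.13. Levels in the background range were those of AT4G29200, AT2G27420, AT5G15360 and AT4G19430 in Col and of AT4G20480, AT1G19530 and AT2G14460 in C24. The 4 anthocyanin genes were higher in C24 after cold, also when adjusted over the list alone, with DFR at 2.35 (camera adjusted p = 0.000951, adjusted p = 0.123 with an estimated correlation). The 3 root-enriched genes were lower, also when adjusted over the list alone, with PYK10 at -0.66 (camera adjusted p = 0.0316, adjusted p = 0.176 with an estimated correlation, 0.138 with dim members left out), and 9 of 14 on the wider root list were lower and 1 higher (camera adjusted p = 0.00373, adjusted p = 0.259 with an estimated correlation).

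Autophagy genes were lower in C24 after cold in 8 of 10 cases and higher in none (camera adjusted p = 0.000169, adjusted p = 0.215 with an estimated correlation), with ATG8E at -2.52. Genes of pathogen defence and salicylate were lower in 10 of 20 cases and higher in 2 (camera adjusted p = 0.00103, adjusted p = 0.206 with an estimated correlation), with ECS1 and WRKY6 (AT1G62300, -1.75) at the lower end. Calmodulin-like and touch genes were lower in 6 of 9 cases and higher in 1 (camera adjusted p = 0.00398, adjusted p = 0.129 with an estimated correlation). Plastid-encoded genes of expression and the NDH complex were higher in 16 of 32 cases and lower in none (camera adjusted p = 0.00419, adjusted p = 0.696 with an estimated correlation). On the wider flavonoid list 8 of 10 genes were higher and 1 lower (camera adjusted p = 0.00103, adjusted p = 0.129 with an estimated correlation), with CHIL at 1.52. Branched-chain amino acid breakdown was lower in 6 of 10 cases and higher in none (camera adjusted p = 0.00273, adjusted p = 0.146 with an estimated correlation). That list and the wider root list were chosen after the leading genes were seen. Ribosome biogenesis and polymerase genes were higher in 12 of 14 cases and lower in 2 (camera adjusted p = 0.011, adjusted p = 0.231 with an estimated correlation). The limma fit called 11218 probe sets, 6388 higher and 4830 lower in C24, and 751 were at least 2-fold higher and 1096 at least 2-fold lower.

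Last, the 24 h response of C24 was tested against that of Col. DFR rose in C24 and fell in Col, a difference of responses of 5.33 ± 0.13 (SE), and COR27 stood at 10.93 before and 10.73 after cold in C24 while rising in Col, a difference of -7.35 ± 0.12. The other leading genes with a higher response in C24 were AT2G27420 (5.35), TBL26 (AT4G01080, 5.02), AT1G22440 (4.14), AT4G30170 (4.13) and APL3 (AT4G39210, 3.76), a subunit of the starch enzyme ADP-glucose pyrophosphorylase. Those with a lower response in C24 were AT3G15450 (-6.26), AT5G62360 (-5.89), AT4G33980 (-5.77), AT3G15630 (-5.61) and AT2G38465 (-4.71). For COR27, AT2G38465 and AT2G27420 1 of the 2 Col levels lay in the background range. The SEs of the 12 differences ran from 0.10 to 0.21, with limma adjusted p-values from 3.86e-11 to 8.78e-08.

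All 4 anthocyanin genes responded more positively in C24, also when adjusted over the list alone (median 3.16, camera adjusted p = 4.18e-05, adjusted p = 0.123 with an estimated correlation), and so did 9 of 10 on the wider flavonoid list with none lower (camera adjusted p = 3.6e-08, adjusted p = 0.0914 with an estimated correlation). Of the COR and LEA genes, COR15B (-2.13), COR47 (-1.35) and COR15A (-0.92) rose less in C24 and LTI30 (0.69) rose more (camera adjusted p = 0.0541). The 3 root-enriched genes had higher responses in C24, also when adjusted over the list alone (camera adjusted p = 0.0127, adjusted p = 0.155 with an estimated correlation, 0.0905 with dim members left out), as did 8 of 14 on the wider root list with none lower (camera adjusted p = 0.00436, adjusted p = 0.273 with an estimated correlation). Autophagy genes had lower responses in C24 in 8 of 10 cases and higher ones in none (camera adjusted p = 0.00067, adjusted p = 0.231 with an estimated correlation), with ATG8E at -3.55. Calmodulin-like and touch genes had lower responses in 7 of 9 cases and a higher one in 1 (camera adjusted p = 0.000703, adjusted p = 0.106 with an estimated correlation), with STZ at -3.48 and CML38 at -2.92. Nuclear photosynthesis genes had lower responses in C24 in 14 of 32 cases and a higher one in 1 (camera adjusted p = 0.00147, adjusted p = 0.106 with an estimated correlation). Glucosinolate and ER-body genes had higher responses in 8 of 15 cases and lower ones in 2 (camera adjusted p = 0.00245, adjusted p = 0.129 with an estimated correlation). The 3 measured glucosinolate genes fixed beforehand had a median of -0.33 and were not called as a list. Dehydrin, LEA and desiccation genes had lower responses in C24 in 11 of 17 cases and higher ones in 5 (camera adjusted p = 0.0204, adjusted p = 0.214 with an estimated correlation), and branched-chain amino acid breakdown had lower ones in 7 of 10 cases and higher ones in none (camera adjusted p = 0.00225, adjusted p = 0.141 with an estimated correlation). The branched-chain list and the wider root list were chosen after the leading genes were seen. Antioxidant enzymes had higher responses in 10 of 17 cases and lower ones in 4 (camera adjusted p = 0.0146, adjusted p = 0.152 with an estimated correlation), with the methionine sulfoxide reductases MSRB9 (AT4G21850) at 2.19 and MSRB6 (AT4G04840) at 1.98. Tau-class glutathione transferases had higher responses in 7 of 11 cases and lower ones in 2 (camera adjusted p = 0.0459, adjusted p = 0.208 with an estimated correlation). With dim members left out, the calls of the antioxidant (adjusted p = 0.0865) and tau-class (0.189) lists were lost.

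The limma fit called 8981 probe sets for the difference of responses, 4636 higher and 4345 lower in C24, of which 2554 differed at least 2-fold. Of the 8981, 4589 also differed in the same direction between C24 and Col after 24 h of cold past the threshold, a count chosen after the data were seen. A probe set that does not detect the C24 transcript would stay flat in C24, so that a Col response alone gives a difference of responses. AT4G15390, for instance, stood at 4.66 before and 4.50 after 24 h of cold in C24. In Col it fell from 10.31 to 7.09, a difference of responses of 3.06. How many of the calls arise from probe sequence was not tested.

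Over all comparisons, 74 of 210 list tests were called with the preset correlation of camera, and 0 with an estimated correlation, where the lowest adjusted p was 0.0914. Of the 30 lists, 8 were called in no comparison, with the lowest camera adjusted p at 0.0541 for the glucosinolate genes fixed beforehand (3 measured), 0.462 for reference genes (4 measured), 0.0761 for jasmonate and defensin genes, 0.0822 for sugar transport and starch, 0.212 for flowering regulators, 0.275 for tubulins, 0.39 for ER folding and 0.515 for auxin response. Median, mean and test differed in sign in 25 of the 210 tests and in 0 of the 74 calls.

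**Figure D3:**
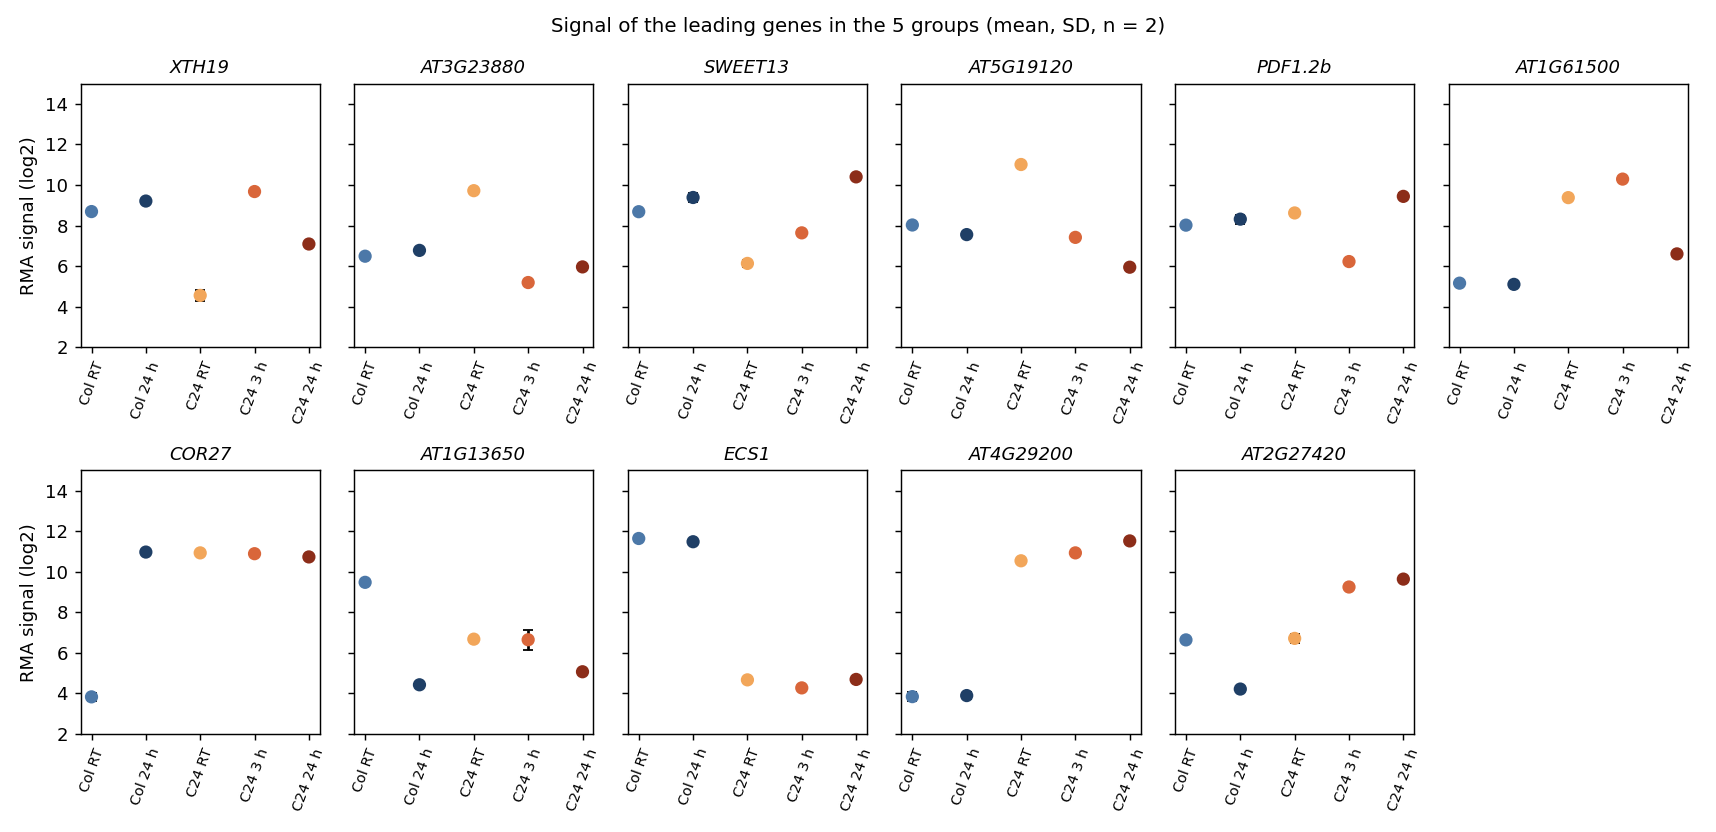
Log2 RMA signal (vertical axis) in the 5 groups for the named gene with the largest rise and the named gene with the largest fall in each comparison, 11 genes in all, RT for room temperature. Points are means and bars SDs of 2 arrays, and COR27 lies at 3.83 in Col at room temperature and between 10.73 and 10.97 in the other 4 groups.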

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

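The tests of root tissue, exchanged labels, harvest time, RNA degradation, probe mismatch and labelling batch, and the measures of how far other scalings moved the probe sets and what shift would even the counts, were chosen only after the result was seen.

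The 24 h response differed between C24 and Col by the limma interaction test at 8981 probe sets. Higher responses in C24 were largest for AT2G27420 (5.35), DFR (5.33), TBL26 (5.02), AT1G22440 (4.14), AT4G30170 (4.13) and APL3 (3.76). Lower responses were largest for COR27 (-7.35), AT3G15450 (-6.26), AT5G62360 (-5.89), AT4G33980 (-5.77), AT3G15630 (-5.61) and AT2G38465 (-4.71). Poly-A spike-in controls, outside the comparisons of genes, were higher on the C24 arrays by 1.33.

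C24 and Col lay further apart at room temperature (root mean square difference of group means 0.761) than after 24 h of cold (0.604), and neither room temperature group was shown to be the odd one. Less root tissue in the C24 room temperature samples could not account for genes at least 4-fold higher in C24, since nuclear photosynthesis genes were higher by a median of only 0.289 (SD 0.482). For the root genes themselves it cannot be told apart from regulation, since the median of the wider root list, -0.952 against Col, passed the bound set for both comparisons, and the median of -0.46 against 3 h missed it. For an exchange of C24 room temperature and 3 h labels, the 100 probe sets that rose most in Col were higher at 3 h by a median of 0.499 (66 of 100 higher). This median met the bound set against an exchange. It did not meet a further rule, that it exceed the SD of 1.33, so an exchange was left open. That SD is the spread between probe sets and not an error of the median. Another harvest time or light state of either room temperature group may also have a part and stays open without a recorded hour, with GI higher in C24 by 1.38, and so does RNA degradation, with the GAPDH 3' minus 5' difference higher than in Col by 0.474 but 1 of its 2 arrays (0.493) below a C24 3 h array (0.568), while an ecotype difference in the plants was not tested.

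Among probe sets with a 4-fold difference at room temperature, 71.2% of 691 were lower in C24. After another quantile normalisation 71.5% were lower, and 69.8% with median centring (lowest 95% limit 66.2). These steps moved the probe sets by medians of 0.0243 and 0.0302, where a shift of 0.39 would even the counts. Scaling differences left between the deposited arrays were thus too small to be the whole cause. Both steps act on values that RMA had already normalised and could move little, so they cannot test the authors' own normalisation. That normalisation and the other steps of the authors' processing stay open. Sequence of C24 that differs from the Col-based probes cannot be told apart from regulation that differs between the ecotypes, since the probe sequences were not analysed here. Of the differences constant over temperature, 75.6% were lower in C24 (31 of 41, 95% interval 59.7 to 87.6), and the interval holds the 70.9% among the other 650.

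The spike-in difference of 1.33 could mark a labelling batch or RNA amount that goes with ecotype. For differences between the ecotypes the batch cannot be told apart from the ecotype, since every C24 array lay above every Col array. A shift shared by all arrays of an ecotype cancels by construction in the difference of responses, where 11.2% of probe sets (2554 of 22746) passed at least 2-fold. Within C24, however, the spike-in means were 7.235 and 7.187 at room temperature and 6.939 and 7.077 after 24 h of cold. In Col they were 5.736 and 5.778, then 5.743 and 5.766. The shift was thus not the same on all C24 arrays, and a part that differs between them does not cancel. The batch of each array is not given in the sources used here, so a batch within an ecotype stays open.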

How the results depend on the processing

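The alternatives that counted calls beyond Col at room temperature or shared with the cold ecotype difference, left out the C24 room temperature arrays or exchanged replicate numbers were chosen only after the result was seen.

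With 1 probe set per gene, which tests fewer probe sets, the calls numbered 5426 (C24 3 h), 5972 (C24 24 h), 5289 (24 h against 3 h), 5993 (Col 24 h), 6964 (ecotypes at room temperature), 6024 (ecotypes in cold) and 4608 (difference of responses). At least 2-fold they were, in that order, 1617, 2496, 1641, 1906, 2543, 1847 and 2554, with overlaps of 854 (C24 3 h with 24 h) and 616 (C24 with Col), by construction. Calls also beyond Col at room temperature numbered 4142 at 3 h and 6714 at 24 h, and 4589 differences of responses went the same way as the ecotype difference in cold.

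With each array left out in turn, where the lone array is assumed to vary like the other groups, calls ranged from 8659 to 10521, 9711 to 11431, 8360 to 10242, 9768 to 11220, 10989 to 12914, 9295 to 11201 and 7796 to 8809, and the overlaps from 5615 to 6692 and 5224 to 5754. The replicate block gave 10311, 11227, 10010, 11142, 12743, 11153 and 8924 calls. Deviations of same-numbered arrays correlated between -0.115 and 0.119 over 10 pairs of groups, so no clear pairing by number was visible in the normalised values. With crossed numbers the ecotypes in cold gave 11091 calls. Without the C24 room temperature arrays, 24 h against 3 h gave 10042 calls, Col 24 h 11220 and the ecotypes in cold 11201.

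All 1504 alternative values of the 94 leading results, each a gene in 1 comparison, kept direction and call. Of 13083 values for 823 results with list examples, 12792 counted as the same, 242 missed the threshold, 49 newly passed it and 0 reversed a called direction. For results short of the threshold in the main fit, a change of direction counted as the same. Against 74 calls among the 210 list tests, an estimated correlation called 0, fry 168, leaving dim members out 60 and the replicate block 76. Leaving dim members out lost 16 of the 74 calls and added 2, and the replicate block lost 0 and added 2. Fry lost 1 and added 95. No scaling reversed the median of a called list. The cause of the losses was not tested. Low signal over background limits what weakly detected genes can show, and a filter on it kept 13072 of 22746 probe sets. Another pseudocount was not run because the values are log2.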

Other observations

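The test of whether the ecotypes lay further apart at room temperature was planned, and its comparison with the other probe sets was chosen only after the result was seen.

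Measured members of lists fixed beforehand that were too short to test also moved. JMT (AT1G19640), the jasmonate methyltransferase, rose by 2.46 ± 0.105 (SE, n = 2) in C24 after 24 h of cold, from the background range, and stood at 0.21 ± 0.105 in Col (limma adjusted p = 0.123), a difference of responses of 2.25. HIS1-3, a linker histone that is also on the tested dehydrin, LEA and desiccation list, fell by 3.43 in C24 and fell by 1.92 in Col. The sucrose phosphate synthase ATSPS4F (AT4G10120) rose by 0.76 in C24 and 0.73 in Col, and the difference of responses was 0.03 ± 0.10. IAA29 (AT4G32280), an auxin-response repressor, rose by 1.48 in Col and 0.54 in C24, where the call was lost without room temperature replicate 1 (limma adjusted p = 0.0527).

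Genes of sugar transport and starch, called as a list in no comparison, held large single changes. APL3 rose by 2.79 in C24 after 24 h, and PWD (AT5G26570), a starch-phosphorylating enzyme, rose by 1.29 in Col and had a response lower in C24 by -1.99. Among antioxidant enzymes, MSRB6 was higher in C24 than in Col after cold by 4.06.

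A hypothesis was that differences of the 24 h response may lie more in the room temperature levels than in the cold levels. Of 2554 probe sets with a 2-fold difference of responses, 63.6% (1624) had the larger ecotype difference at room temperature, against 56.2% of the other 20192 probe sets, so part of this share is general. The 2554 were selected on the gap between these same 2 ecotype differences, which were larger at room temperature over all probe sets. The excess over the other probe sets is therefore partly built in, and the comparison cannot decide the hypothesis. Of the 2554, 1006 differed 2-fold between the ecotypes only at room temperature, 530 only after cold, 9.51% at both the same way, 142 at both in opposite directions and 633 at neither.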
